A study of Mus musculus with 12 samples.

How the data were processed

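Poly(A) RNA from HT22 cells, an immortalised mouse hippocampal line, was sequenced in 12 libraries. Per the labels' protocols, all cultures started from the same plating density and were harvested at the same confluency, and libraries were made with a NEBNext Ultra II kit. The labels describe 1 wild-type clone and 3 mutant clones, numbered 2, 3 and 4, with 3 technical replicates of each clone. The mutant clones carry a deletion of the SET domain of KMT2D, the catalytic domain of this histone methyltransferase. The columns and sample titles number the mutant clones 1, 2 and 3, and these are mutant clones 2, 3 and 4 of the sample type labels, whose numbers are used throughout. Columns were matched to samples by title.

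The deposited table holds expected counts, that is, estimated counts that need not be whole, for 28113 features in 12 columns. Only 1.49% of the non-zero values lay within 0.001 of a whole number, while 58.6% of those below 10 lay within 0.1 of one. Salmon, edgeR, limma, DESeq2 and the mouse build GRCm38 are named in the submitters' processing notes. Which of these steps made the deposited values, whether the estimates were scaled, and the tool versions, annotation and filters are not given in the sources used here. The table as used here has 0 columns of gene identifiers, and gene names were not inferred from the order of the features. The targeted gene, genes by symbol, gene lists, markers of other cell types and medians per chromosome, all planned before the data were examined, were therefore not analysed here. Features are named by their place in the table.

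Estimated counts were rounded to whole numbers. Totals per library ranged from 25711054 to 50473355, and 3141 features were at 0 in every library. CPM values, counts scaled by library size, were computed with the trimmed mean of M values (TMM). They served for levels, for CPM and fold limits and for positions between clones, not as input to the tests. Correlations between libraries and principal components used log2 CPM scaled by library size alone, without TMM. Tests used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM, the filterByExpr filter and Benjamini-Hochberg adjustment, with an adjusted p threshold of 0.05. Genotype was tested on counts summed over the libraries of each clone, since the clone is the biological replicate, with 1 wild-type clone and 3 mutant clones. That test assumes that the single wild-type clone varies as the mutant clones do. Each mutant clone was also compared with the wild-type clone, and the mutant clones with each other, in a fit of all 12 libraries with 1 shared estimate of the spread. The p-values of that fit measure the spread of technical replicates and compare particular clones, not genotypes. After filtering, 17462 features were tested in the clone sums and 14642 in the fit of libraries.

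The planned rule for named genes took features with a mean of at least 5 CPM that passed the threshold in the same direction in all 3 clone comparisons, ranked by the smallest absolute log2 fold change over the clones. Its limits on symbols could not be applied, and the first 2 higher and the first 2 lower features are given. For comparisons at equal depth, libraries were thinned to 25711054 counts. A position between 2 clones was estimated for each library from features that differed between the clones by at least 8-fold, and again from those differing by 2 to 8 times with at least 20 CPM. In both sets the library itself was left out of its own clone's mean.

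Tests were tried on simulated counts drawn from the real means and library sizes with 200 changed features. These were drawn from features with a mean of at least 1 CPM, so the shares recovered do not cover features under 1 CPM. In the fit of libraries for clone 2 against the wild-type clone, 62.7% of features changed by 1.5-fold, 88.1% of those changed by 2-fold and 98.5% of those changed by 4-fold were recovered, among 14411 tested. For the clone sums these shares of the changed features were 5.97%, 47.8% and 93.9%, among 14640 tested. There the simulated clone-to-clone dispersion followed a smooth trend, without features of unusually high or low spread. The real test did not call features with log2 fold changes of 3.43 and -3.27, so these shares do not say what it would recover. In the fit of libraries, the shares for features changed the same way in all 3 mutant clones were 52.2%, 88.1% and 95.5%. For differences among the mutant clones they were 74.6%, 86.6% and 97.0%. Mixing 20% of clone 3 into counts of clone 4 replicate 2, without added replicate spread, was recovered as 17.8% and 22.8% in the sets of larger and smaller differences.

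Alternatives chosen before the data were examined were size factors of DESeq2, no filter on low counts, DESeq2 1.42.0 as the test, limma 3.58.1 voom with clone as a random block, the libraries as separate samples, the replicate number as a block, a 2-fold limit, the 6 libraries of a comparison alone, and leaving out each clone or library in turn. Thinning, the number of detected features as a covariate, the CPM minimum for 2-fold counts and the other tools for each clone in turn were added after the data were seen. The 16-fold limit for features nearly lost in 1 clone was also chosen then.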

Results

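Gene expression was measured by RNA sequencing in HT22 cells, a mouse hippocampal line, from 1 wild-type clone and 3 clones lacking the SET domain of KMT2D, a histone methyltransferase. Each clone gave 3 libraries that the labels call technical replicates, 12 in all. Total estimated counts were 46827470, 38892855 and 47437403 for replicates 1, 2 and 3 of the wild-type clone, 38274294, 40711013 and 34895852 for mutant clone 2, 50473355, 33298805 and 25711054 for mutant clone 3, and 49100951, 37693927 and 45122619 for mutant clone 4. The comparisons ask which transcripts differ between wild-type and KMT2D-deficient cells. With a single wild-type clone, a difference of genotype and an individual trait of that clone are confounded.

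Libraries of the same clone correlated with r from 0.983 to 0.990 across features, and libraries of different clones with r from 0.966 to 0.986. Features are not independent replicates, so these values only describe similarity. Each pair of libraries within a clone differed by more than sampling noise, with a chi-square per feature between 6.71 and 115, so no library was counted as a duplicate. The highest values, 115 and 81.1, were those of wild-type replicate 3 with replicates 1 and 2 of its clone. All other pairs within a clone were at 25.6 or less. The value of 115 exceeded some values between clones, such as 84.7 for wild-type replicate 1 with clone 3 replicate 1. With all libraries thinned to 25711054 counts, the wild-type clone had 19159 ± 717 detected features, mutant clone 2 had 19166 ± 392, mutant clone 3 had 18030 ± 671 and mutant clone 4 had 18359 ± 583 (SD, n = 3 technical replicates). Wild-type replicate 3 had the highest number, 19987, and mutant clone 3 replicate 3 the lowest, 17478. The first 3 principal components held 29.8%, 18.2% and 13.4% of the variance. On the first component wild-type replicate 3 and mutant clone 3 replicate 3, the libraries with the most and the fewest detected features, lay at opposite ends.

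**Figure D1:**
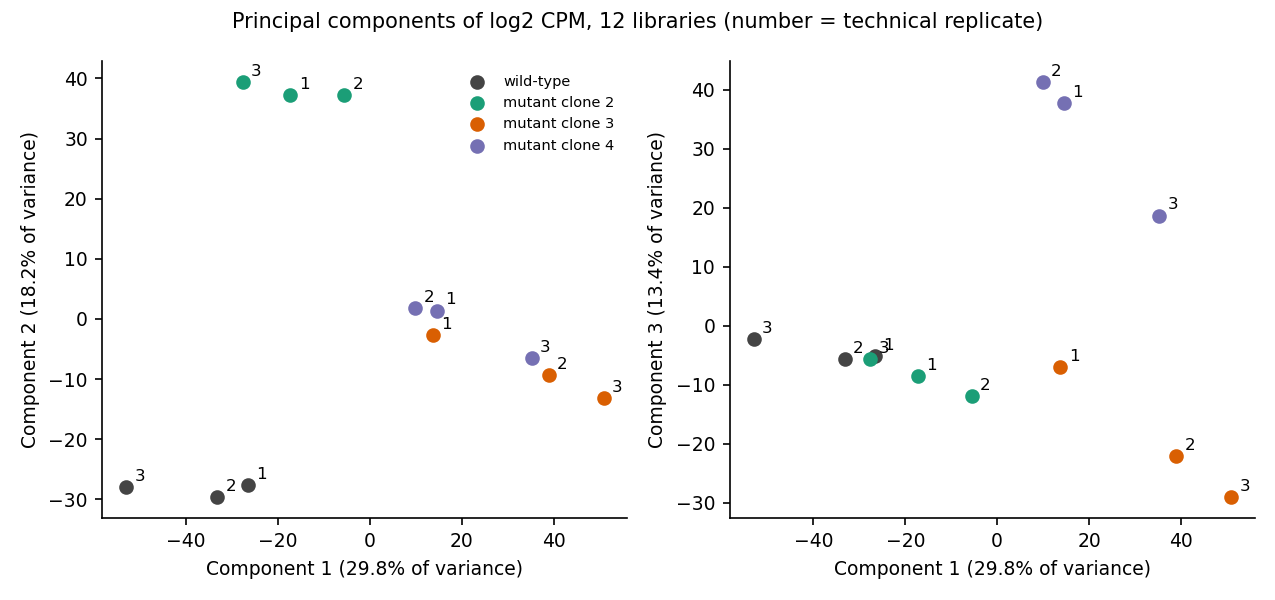
Principal components of log2 CPM for the 12 libraries, component 1 against components 2 and 3, with colours for clones and numbers for technical replicates. Components 1, 2 and 3 hold 29.8%, 18.2% and 13.4% of the variance.

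Across clones, 0 of 17462 features differed between the 3 mutant clones and the wild-type clone by edgeR on the clone sums, with a smallest adjusted p of 0.104. At an unadjusted p under 0.05 there were 1382 features, 544 higher and 838 lower in the mutant clones, where 873 would be reached by chance. Other tools called more: DESeq2 on the same sums gave 253, of which 189 were lower, and limma with clone as a random block gave 576, of which 437 were lower. Without a filter edgeR gave 20, and without mutant clone 2 it gave 50. The limma fit used the 12 libraries, not the sums, with a consensus correlation of 0.437 between libraries of a clone. Technical replicates therefore count there in part as separate samples. The call across clones depended on the tool or its input. The biological coefficient of variation was 22.8% in the clone sums, over 17462 features, against 11.7% among libraries of a clone, over 14642 features. The single wild-type clone adds no spread to the first value, which reflects the 3 mutant clones only.

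Compared clone by clone, many features separated each mutant clone from the wild-type clone beyond the spread of technical replicates. Mutant clone 2 had 1969 higher and 2645 lower features, mutant clone 3 had 1648 and 1649, and mutant clone 4 had 2067 and 2106, of 14642 tested with edgeR. Larger differences were mostly lower values: at 2-fold or more, 161 features were higher and 540 lower in clone 2, 80 and 569 in clone 3, and 140 and 572 in clone 4. The count for clone 3 was sensitive to the fit. It was 3297 in all, 1767 (697 higher and 1070 lower) from the 6 libraries of both clones alone, 2151 without clone 3 replicate 3, and 1433 (499 higher and 934 lower) with the number of detected features as a covariate. In the last of these fits 65.2% of the features were lower, where the fit without the covariate split evenly.

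**Figure D2:**
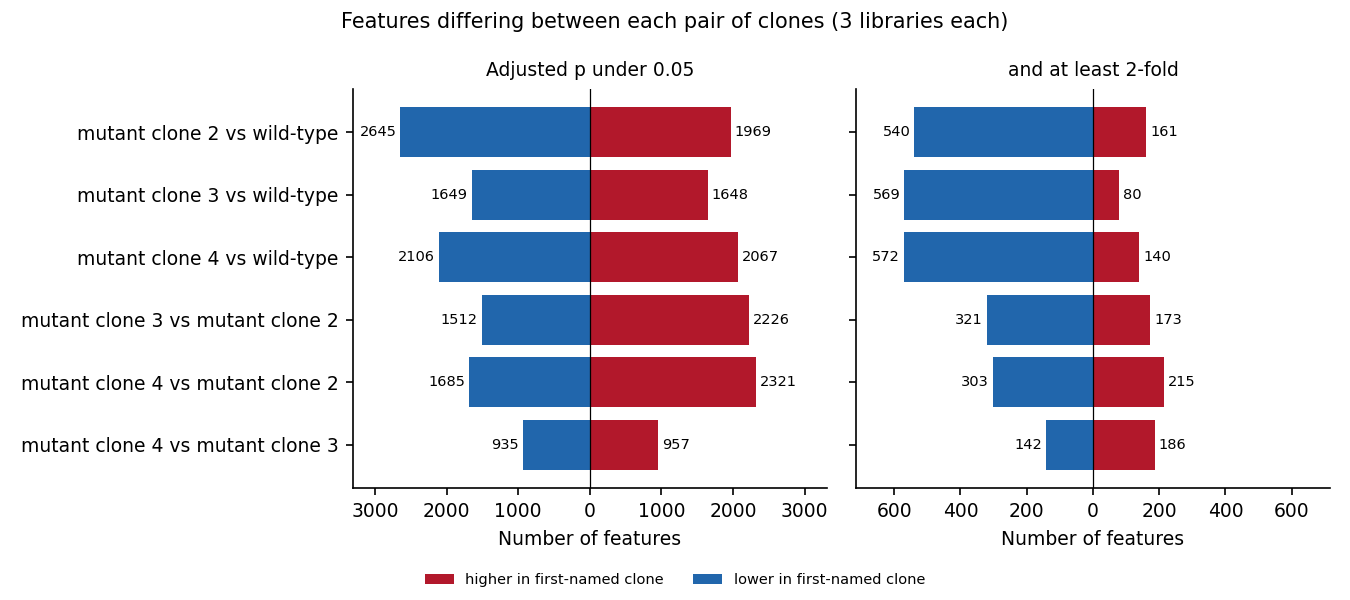
Numbers of features differing between each pair of clones by edgeR on 3 libraries per clone, with bars to the right for features higher in the first-named clone and to the left for lower ones. The left panel counts all features past the adjusted p threshold and the right panel those that also differ by at least 2-fold, such as 161 higher and 540 lower in mutant clone 2 against the wild-type clone.

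Features that differed the same way in all 3 mutant clones numbered 585 higher and 787 lower. Independent lists of these sizes would share 31.3 and 42.8. Clones simulated without any difference between clones, the wild-type libraries included, shared 0. Without clone-to-clone variation, that simulation is no baseline for clones that differ individually. Mutant clone 2 stood apart from each of the other clones in 1581 features. Because the wild-type libraries are too few to be split, part of the excess may come from the shared controls. The mean covariance of the log2 fold changes between clones was 0.275 against 0.0513 in the simulation, a difference of 0.224. The mean correlation was 0.591 against 0.501. With mutant clones 2, 3 and 4 as the reference, the covariance exceeded the same simulated value by 0.161, 0.154 and 0.0995. The mean correlations were then 0.503, 0.495 and 0.393. A shared reference alone gave 0.501 in the simulation, so a correlation near that value shows no common effect. The covariance takes in individual differences of the reference clone, which the simulation lacked. These excesses therefore cannot separate genotype from such differences. The simulation took the simulated wild-type libraries as the reference. Among the shared features that differed by at least 2-fold in each clone, 12 were higher and 221 lower. Without wild-type replicate 1 the higher features numbered 22, against 208 lower. The 221 lower features had low levels, with medians of 1.98 CPM in the wild-type clone and 0.430, 0.332 and 0.388 CPM in mutant clones 2, 3 and 4. With a mean of at least 5 CPM, 1 higher and 35 lower features were left. With the number of detected features as a covariate, the shared features fell to 249 higher and 575 lower, so the lower share moved from 57.4% to 69.8%.

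The feature at table row 2508 was at 1.05 ± 0.063 CPM in the wild-type clone (SD, n = 3 technical replicates) and at a mean of 11.3 ± 3.29 CPM in the mutant clones (SD, n = 3 clones). Its log2 fold changes were 2.84 ± 0.104, 3.69 ± 0.104 and 3.60 ± 0.104 (SE) in clones 2, 3 and 4, each past the threshold of edgeR. Table row 27681 was at 15.7 ± 5.19 CPM in the wild-type clone and 31.6 ± 1.83 CPM in the mutant clones. Table row 14968 was lower, with 20.4 ± 9.18 CPM in the wild-type clone and 1.66 ± 0.869 CPM in the mutant clones, as was table row 6682, with 67.5 ± 5.88 and 6.86 ± 2.98 CPM. All 4 features passed the threshold in each of the 3 clone comparisons, as the rule that chose them required. None passed it across clones, where edgeR gave adjusted p of 0.201, 0.209, 0.236 and 0.163 in the same order, with log2 fold changes of 3.43, 1.04, -3.59 and -3.27, whereas all 4 passed with DESeq2 on the same sums.

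Clones of the same genotype also differed. Among the 3 mutant clones 5017 features, 34.3% of those tested, passed the threshold of edgeR, of which 782 had a difference of at least 2-fold between some pair of clones. Clone 3 differed from clone 2 in 3738 features, clone 4 from clone 2 in 4006 and clone 4 from clone 3 in 1892. Both comparisons with clone 2 fell in the range of those with the wild-type clone, but at 2-fold or more they gave 494 and 518 features, and clones 4 and 3 gave 328, fewer than the 701, 649 and 712 of clones 2, 3 and 4 against the wild-type clone. The count for clones 4 and 3 fell without any 1 library of these clones. It was 1342, 1180 and 1287 without clone 3 replicates 1, 2 and 3, and 1117 and 1087 without clone 4 replicates 1 and 2. Without clone 4 replicate 3, which lay 20.5% of the way toward clone 3 over features that separate these clones, it was 1610. Each of these fits had 1 library fewer, so a loss of sensitivity and a trait of that library were not told apart. Without wild-type replicate 3 the count for clones 4 and 3 was 2844, though that library enters only through the filter, the scaling and the shared estimate of the spread.

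**Figure D3:**
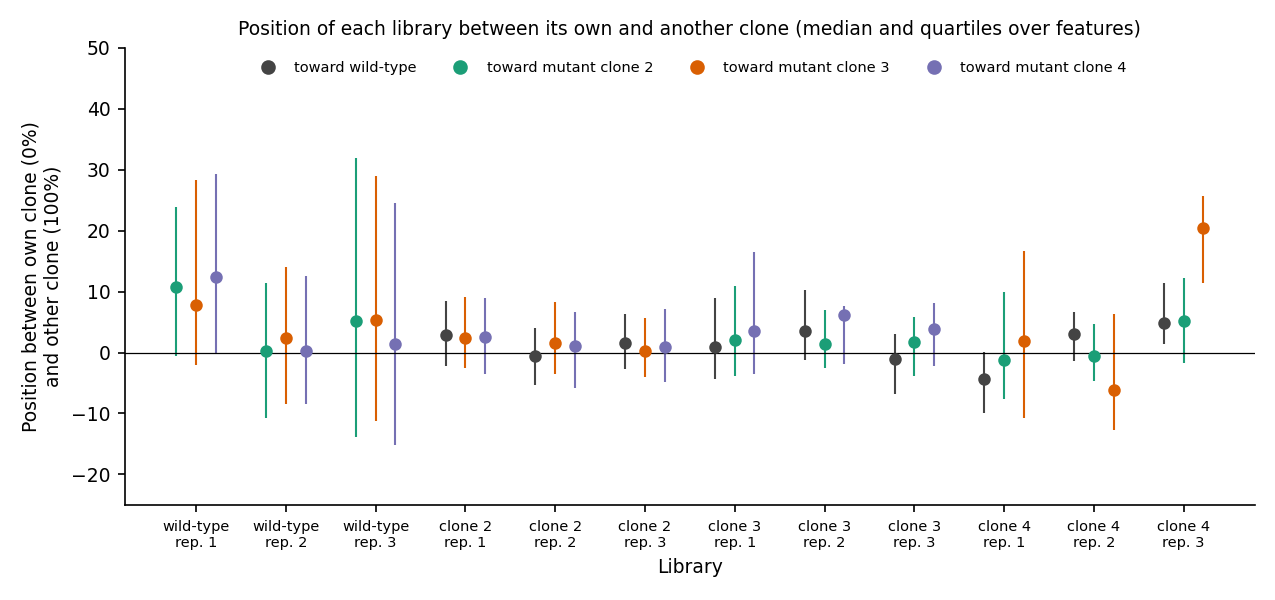
Position of each library between its own clone (0%) and each other clone (100%), as the median and quartiles over features that differ by 2 to 8 times, with the colour for the other clone. Mutant clone 4 replicate 3 lies at 20.5% toward clone 3, and the highest of the 35 other positions is 12.4%.

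To place the wild-type clone among the others, each clone was set in turn against the other 3. Features higher or lower in 1 clone than in each of the others numbered 787 and 585 for the wild-type clone, 485 and 1096 for mutant clone 2, 134 and 228 for mutant clone 3, and 320 and 316 for mutant clone 4. The wild-type clone was thus not the most distinct clone by this count, since mutant clone 2 had 1581 such features against 1372. At 2-fold or more the wild-type clone had 221 higher and 12 lower features, against 52 and 62 for clone 2, 10 and 61 for clone 3 and 28 and 59 for clone 4. With a mean of at least 5 CPM as well, it had 35 and 1, against 11 and 28, 0 and 20, and 7 and 21. By the total of both directions mutant clone 2 then had slightly more features than the wild-type clone. On the clone sums, edgeR called 0, 1, 0 and 0 features for the wild-type clone and mutant clones 2, 3 and 4, with 1382, 1325, 453 and 608 at an unadjusted p under 0.05. DESeq2 called 253, 256, 52 and 55, and limma 576, 538, 7 and 35. The limma counts came from the 12 libraries with clone as a random block, not from the clone sums. With 4 clones the wild-type clone cannot stand apart with a share under 1 in 4.

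**Figure D4:**
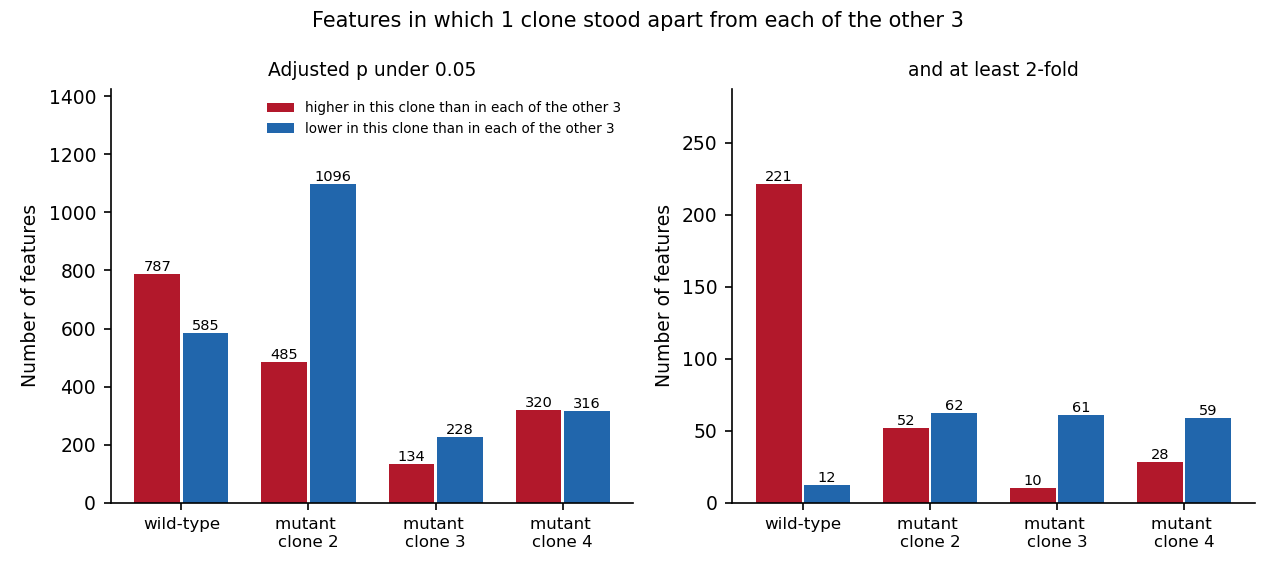
Numbers of features higher or lower in 1 clone than in each of the other 3, for each clone in turn, at the adjusted p threshold and also at 2-fold or more. At 2-fold or more the wild-type clone has 221 higher and 12 lower features, and mutant clone 2 has 52 and 62.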

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

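Of the tests in this part, leaving out clone 4 replicate 3 was chosen as an explanation after the result was seen, and thinning and the covariate for detected features were added after the data were seen.

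The mutant clones, which share a genotype, differed from each other in 5017 features by edgeR, tested on technical replicates. Set against the same wild-type clone, 399 features passed the threshold in opposite directions in 2 mutant clones with the difference itself past the threshold. Groups of 3 libraries are too small for a check of single outlying values. Of 100 groupings of the 9 mutant libraries into 3 groups, 1, the real one, gave 5017 features or more. The highest of the others gave 2189. The other groupings mix technical replicates of different clones, so this shows only that libraries of a clone belong together. Thinning to equal depth gave 4813 features, the number of detected features as a covariate gave 3994, and leaving out clone 4 replicate 3 gave 4488. Each argues against depth, detection or that library as the whole cause. Differences that arose when the clones were isolated or grown may remain as an explanation beside the 4813 features at equal depth, and the labels name no culture or library batch, so batch was not tested.

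For each mutant clone against the wild-type clone, the 6 libraries allow only 10 splits, too few for a share under 0.05. Each split was fitted with all 12 libraries, the other 6 keeping their clones. In each of the 3 comparisons 1 split, the real one, gave the most features, 4614, 3297 and 4173 for clones 2, 3 and 4, and the highest of the others gave 0, 1 and 0. For the 1372 features shared by all 3 mutant clones, 1 of 100 groupings of the 12 libraries, the real one, gave as many, and the highest of the others gave 778. With the clones kept whole and mutant clone 2 as the reference the count was 1581, a grouping not among the 100. The 100 groupings therefore show that libraries of a clone belong together, not that genotype sets the wild-type clone apart. They do not exclude a difference between clones unrelated to genotype.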

How the results depend on the processing

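Thinning, the covariate for detected features, the CPM minimum and every alternative for the 2-fold shared counts were chosen after the data were seen; the rest were planned. The 0 features across clones by edgeR stayed at 0 with DESeq2 size factors. A 2-fold limit could only leave them at 0. They became 20 without a filter, 253 with DESeq2, 576 with limma and clone as a random block, and 2000 with the 12 libraries as separate samples, or 1667 with the replicate block added. The last pair treats technical replicates as independent. The limma fit also used the 12 libraries, so replicates count there in part as separate samples. For all but the last pair the cause was not tested. Leaving out a clone or library gave 0 to 50, the highest without mutant clone 2. Requiring 2-fold left 701, 649 and 712 features for clones 2, 3 and 4, 233 shared and 782 among mutant clones, by construction. With detected features as a covariate clone 3 had 1433 and the shared count was 824; the 6 libraries alone gave clone 3 1767. The cause was not tested. A mean of at least 5 CPM left 35 lower and 1 higher of the 2-fold shared features. Without single libraries, clone 3 ranged from 2151 without its replicate 3 to 3511, and the 2-fold higher shared features from 10 to 22, the highest without wild-type replicate 1. Ranges within 1.5 times were 3745 to 5183 for clone 2, 3115 to 4475 for clone 4, 1045 to 1526 shared, 196 to 222 for the 2-fold lower shared features and 3995 to 6544 among mutant clones. The 1892 features between clones 4 and 3 ranged from 1087 without clone 4 replicate 2 to 2844 without wild-type replicate 3. The 4 named features kept their direction under all alternatives run, and each passed the threshold across clones in 4 to 6 of them. Those included both fits with the 12 libraries as separate samples. The features were chosen for large shared differences in the same data, so this is no independent support. DESeq2 size factors, no filter and DESeq2 kept the 5 counts of the fit of libraries within 1.5 times. Correlations of deviations between libraries of the same replicate number ran from -0.216 to 0.266, with 3 of 18 pairs over 0.1. They thus had no common sign. Libraries of different numbers were not compared in this way, so pairing is not excluded. The replicate block gave 4796, 3429, 4329, 1464 and 5143 for clones 2, 3 and 4, the shared features and the mutant clones. These 5 counts were each higher than without the block. The block changed no other count by over 1.5 times. Alternatives for gene lists and genes by symbol were not run, as the features carry no identifiers here. Of 3084 features under 1 CPM 4.60% were shared, against 12.7% of 2281 at 100 CPM and more; whether depth sets this was not tested.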

Other observations

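In this part some tests were chosen after the results were seen. They were those of carry-over, of wild-type replicate 3, of the detection floor and of the wild-type clone as an individual. Thinning, the covariate for detected features and the 16-fold limit were added after the data were seen.

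Most of the 2-fold differences shared by all 3 mutant clones were lower values, 221 against 12. At equal depth the lower features numbered 184 against 11 higher ones, with detected features as a covariate 174 against 9, without wild-type replicate 3 they numbered 196 against 18, without wild-type replicate 1 they numbered 208 against 22, and with a mean of at least 5 CPM they numbered 35 against 1. These counts argue against depth, detection, either of these libraries or the detection floor as the whole cause. When each mutant clone was set against the rest, at most 52 features were at least 2-fold higher in it alone, fewer than 221, but with 1 wild-type clone an individual trait of that clone and its genotype cannot be told apart. A loss of expression that depends on KMT2D may contribute, as a hypothesis that 1 wild-type clone cannot test.

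Mutant clone 4 replicate 3 lay between its own clone and mutant clone 3. Over 33 features that differ by 2 to 8 times between these clones its median position was 20.5% of the way toward clone 3 (quartiles 11.4% and 25.7%). At equal depth, which leaves detection unequal, it was 21.8%, and over features that differ by at least 8-fold it was 18.4% in 8 features low in clone 3 and 20.1% in 5 low in clone 4, which argues against depth. Without thinning, the highest of the 35 other positions over features differing by 2 to 8 times was 12.4%, for wild-type replicate 1 toward clone 4, and clone 4 replicate 3 had 17692 detected features at equal depth, against 18618 and 18768 in the others of its clone and 18777, 17835 and 17478 in clone 3. Carry-over of RNA or reads from clone 3 may account for this, but the position toward clone 2 was 5.24%, over the 5% limit set for that explanation, so carry-over, lower detection and a different state of this culture cannot be told apart.

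Single features separated clones almost completely. A feature counted as nearly lost if at least 16-fold lower in 1 clone, with at least 5 CPM in every library of the others. By this limit 1 feature was nearly lost in mutant clone 2, at 0 CPM against at least 8.10 CPM in the other clones. In mutant clone 3 it was also 1 feature, at 0.073 CPM against at least 7.56 CPM. The wild-type clone and mutant clone 4 had 0 such features.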
